A study of Sus scrofa with 28 samples.

How the data were processed

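RNA from the semimembranosus, a muscle of the ham, was measured in 14 pigs on nylon cDNA arrays. Per the labels' protocols, total RNA was copied into cDNA carrying radioactive phosphorus, each pig's cDNA was hybridised to 1 array that carries the same probes in a left and a right part, and the spots were quantified on a phosphor image through a grid of fixed spot diameter (BZscan). A hybridisation with an oligonucleotide common to all spots came first, to check the amount of DNA per spot. Whether the deposited values were divided by that first signal is not given in the sources used here, nor is any background correction. The deposited values are spot intensities on a linear scale, 4608 probes by 28 columns, from 0.0393 to 443.3, with 0 missing values. Every column was used. The columns were matched to pigs and array parts by their sample, and the groups follow the labels, with 7 normal pigs (low L*, a darker meat) and 7 pigs with destructured meat (high L*, a paler meat). The pig is the replicate, and the left and right parts repeat the same RNA on the same membrane. The number of arrays limits the precision.

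Intensities were taken to log2. The column medians spanned 1.12 on that scale, from 1.69 to 3.67 in linear intensity, so by a rule set before the data were examined the 28 columns were quantile normalized. The left and right parts were then averaged per pig. Destructured was compared with normal by limma (lmFit and eBayes, limma 3.58.1 in R 4.3.3), with the group as the only term, no filter on dim probes, and Benjamini-Hochberg adjustment over all 4608 probes at a threshold of 0.05. The labels state no test. Fold changes are destructured minus normal on the log2 scale, with the standard error (SE) of the moderated fit. Gene lists were tested with camera (preset correlation 0.01) over the lists with at least 5 measured genes, taking the brightest probe per gene, with fry and camera with an estimated correlation beside it. The separation of the groups over the whole profile was tested by an exact one-sided permutation test of the mean between-group minus mean within-group distance, the distance being 1 minus the Pearson correlation of probe-centred values. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

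Gene names came from the platform annotation, which is old. It gave 1 symbol to 509 probes and several to 1 probe, which names no gene here. The other 4098 probes are unnamed here. The 509 probes stand for 211 symbols, 79 of them with at least 2 probes. The Entrez identifiers of 496 of the 509 were found in the RefSeq gene table, and symbols otherwise stand as in the annotation. 1 gene entered a list through a RefSeq synonym (HSP70.2). The genes named were chosen by a rule set beforehand. Up to 12 genes per direction past the threshold are named by size of change; where fewer than 24 pass in all, every passing gene is named and the rest up to 20 are those with the smallest p, stated not to pass. The 3 members of each list with the smallest p, taken over all probes of a gene, are named as well, so a named probe need not be the brightest one that entered the list. For each named gene the other probes were checked.

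The fit was tested on simulated data with the real probe means and spreads and 200 changed probes among 4608, for destructured against normal. It recovered 36% of 50 probes changed by 0.5 on the log2 scale, 82% of those changed by 1, 96% of those changed by 1.5 and 100% of those changed by 2, with 10 false calls. With no probe changed it made 0 calls. The simulated noise was normal and independent between probes, with no position pattern, no displaced array part and no scaling step. These counts therefore do not give the rate of false calls in the real data.

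Alternatives planned before the data were examined covered the scaling, a filter on dim probes, each array part alone, the pig number found in both groups, each pig left out, the variance model, array weights, the offset before log2, the threshold, the test and the treatment of several probes per gene. Keeping only probes complete in all 28 columns removed none. In all 37 settings were run, 32 planned and 5 added after the data were seen. The added ones leave out the right part of the array of normal replicate 3, move that part back by its best row offset, remove position medians, combine the first and the last of these, or add array brightness to the fit. Scaling, exclusion and position correction were explored before the final computation was written, and the main setting stayed as fixed beforehand. During that exploration regular re-orderings of the rows were also searched for one that would match names to values better, including a much larger family than the offsets and reversals reported here; none was adopted, and no gene was named from one.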

Results

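The study compared muscle RNA between pigs whose semimembranosus gave normal meat and pigs whose meat was destructured, a pale defect of cooked-ham muscle that the submitters graded by the lightness value L*. Each of the 7 normal and 7 destructured pigs had 1 array with 2 parts. The array medians on the log2 scale were 1.31 ± 0.306 (SD, n = 7) in normal and 1.52 ± 0.161 (SD, n = 7) in destructured pigs, a difference of 0.22 that did not pass an exact two-sided permutation test (p = 0.128). In the labels normal replicate 2 and destructured replicate 3 carry the same pig number, and nothing says whether it is 1 animal.

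The comparison of destructured with normal muscle called 30 of 4608 probes, 25 higher and 5 lower in destructured pigs, with log2 fold changes from -1.46 to 1.10. Among them 4 carry a gene name. The probe listed for TMBIM6, which encodes a membrane protein of the endoplasmic reticulum that restrains cell death, was lower in destructured muscle, at -0.10 ± 0.13 against 1.36 ± 0.476 in normal muscle (mean log2 intensity ± SD, n = 7 each), 2.75-fold (log2 fold change -1.46, SE 0.18, adjusted p = 0.00106). Higher in destructured muscle were the probes listed for TXNIP, the thioredoxin-interacting protein, by 1.73-fold (0.79, SE 0.15, adjusted p = 0.0322), for VDAC1, a channel of the outer mitochondrial membrane, by 1.72-fold (0.78, SE 0.17, adjusted p = 0.0402), and for RPS3, a protein of the small ribosomal subunit, by 1.61-fold (0.69, SE 0.14, adjusted p = 0.0343). All 7 destructured pigs lay on the same side of the normal mean for each of these 4 probes. The same held for the rest of the 20 named genes with the smallest p, which did not pass, so it does not set the called probes apart. At an unadjusted p under 0.05 stood 601 probes, where 230.4 would be reached by chance.

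**Figure D1:**
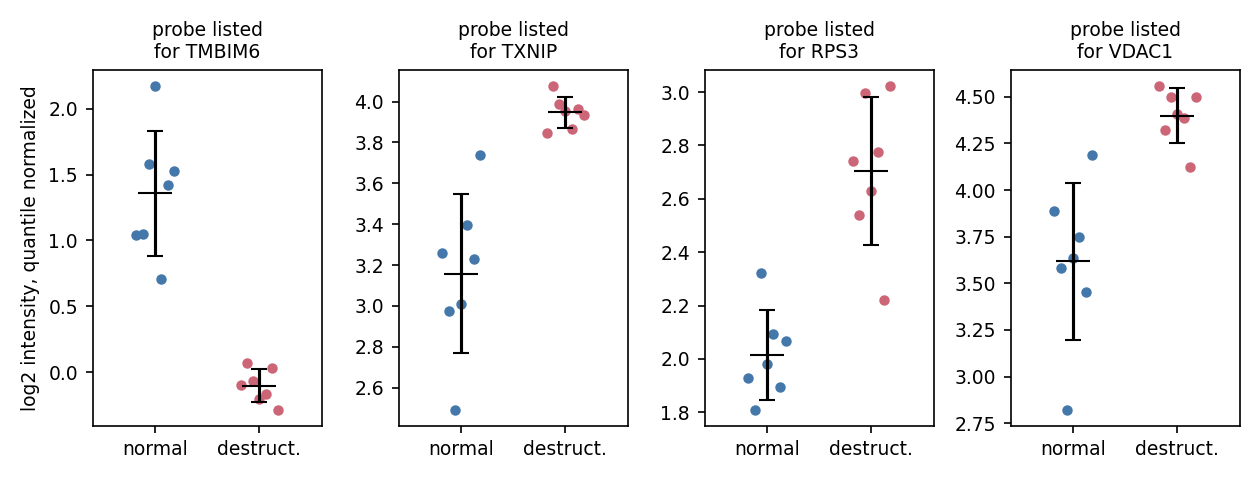
Quantile-normalized log2 intensity (y axis) of the 4 named probes past the threshold, one point per pig, 7 normal pigs on the left and 7 destructured pigs on the right of each panel; bars are the mean ± SD and each panel has its own y range. The probe listed for TMBIM6 averaged 1.36 in normal and -0.10 in destructured pigs, and the other probes were higher in destructured pigs.

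The gene names need caution. Over the 377 probes of the 79 genes with several probes, the mean log2 intensity was not shown to vary between genes beyond what shuffled names gave (F = 1.15, permutation p = 0.206, 10000 shuffles). In table columns 2 to 7 alone, which hold 167 such probes, it did vary more between genes (F = 1.68, permutation p = 0.0208), and in the remaining columns this was not shown (F = 1.22, permutation p = 0.209); these 3 sets of probes were looked at after the data were seen, and 0.0208 is not adjusted for them. Clones of 1 gene can differ in spot signal, so these levels do not decide whether names and values are aligned. Across pigs, where that signal cancels, probes listed for the same gene correlated at a mean of 0.010, which was not shown to exceed shuffled names (median 0.0052, permutation p = 0.432). Each gene below is therefore "the probe listed for" that gene. The second probe listed for TMBIM6 had a log2 fold change of 0.10, against the called one, and the other 4 probes listed for RPS3 ranged from -0.18 to 0.14. TXNIP and VDAC1 have 1 probe each.

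The number of called probes depended on single pigs, on scaling and on 1 array part. On the deposited scale 2 probes were called (1 higher, 1 lower) and with median centring 6 (2 higher, 4 lower), so most calls of higher probes were lost. All 25 higher probes kept their direction in both, with a median log2 fold change of 0.92 and 0.71 against 0.75 and a median SE of 0.25 and 0.17 against 0.15. More higher than lower probes were called without the dimmest 25% (42 and 7) and 50% of probes (49 and 7), with the offset (45 and 8) and with array weights (110 and 19). That excess was small or absent with trend and robust variances (2 and 4) and from the left (7 and 6) and right part (0 and 1). It was absent too with position medians removed (1 and 4), with brightness in the fit (0 and 1) and without the samples that share a pig number (0 and 3). Leaving out 1 pig at a time gave from 2 calls, without destructured replicate 3, to 84, without normal replicate 3, and only normal replicate 6 and destructured replicate 6 left the count within 1.5 times. The right part of the array of normal replicate 3 correlated with its left part at only 0.380; without that part, an exclusion chosen after the data were seen, 135 probes were called (116 higher, 19 lower), including 29 of the 30. With position medians removed, also chosen afterwards, 5 were called, and with both changes 17; the 25 higher probes all kept their direction, with a median log2 fold change of 0.63 (median SE 0.15) and 0.57 (median SE 0.13). The probe listed for TMBIM6 passed in all 28 alternatives that kept it (adjusted p from 1.95e-06 to 0.0105), with log2 fold changes from -1.59 to -0.94. The filters on dim probes left it out, as its mean level lies in the dimmest 25%. Signal over background is not given, so how far its fold rests on a signal near the floor could not be told. Those listed for TXNIP, RPS3 and VDAC1 kept their direction in 30 alternatives and passed in 12, 13 and 11 of them. Without the right part of normal replicate 3 their log2 fold changes were 0.61, 0.74 and 0.66 (SE 0.12 each), and all passed. For TXNIP and VDAC1 these are smaller than the 0.79 and 0.78 of the main comparison. In it normal replicate 3 was the lowest normal pig for both (2.49 and 2.82).

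Of the 20 genes named by the rule, the other 16 did not pass. The probes with positive log2 fold changes were those listed for FAU (0.86, SE 0.20, adjusted p = 0.0549), CALM3, a calmodulin gene (0.66, SE 0.17, adjusted p = 0.0708), GAPDH, a glycolytic enzyme (0.69, SE 0.18, adjusted p = 0.0744), the fast troponin I gene TNNI2 (0.45, SE 0.13, adjusted p = 0.0967), the ferritin light chain FTL (0.38), the slow myosin heavy chain MYH7 (0.56), IGFBP2, which binds insulin-like growth factors (1.03, SE 0.31, with destructured replicate 7 at 4.53 and the next pig at 2.79), the fast myosin light chain MYLPF (0.39) and RPS3A (0.37). Negative values were found for the probes listed for the fast troponin T gene TNNT3 (-0.42, SE 0.12, adjusted p = 0.104), PPP1R12A (-0.46), HSP90AA1, a chaperone (-0.41), the muscle creatine kinase CKM (-0.66), HADHA of fatty acid oxidation (-0.51), FCN1 (-0.37) and COX8H, a cytochrome c oxidase subunit (-0.83, SE 0.28, adjusted p = 0.178). All of these negative probes lie in table columns 10, 11 and 1, where probes had negative fold changes on average. Of the positive ones, CALM3 and GAPDH lie in column 10. With position medians removed the negative probes kept their sign, from -0.52 for CKM to -0.10 for HADHA, and none passed. Without the right part of normal replicate 3, the probes listed for CALM3 (adjusted p = 0.0110), FAU (0.0169), TNNT3 (0.0320), FTL (0.0363) and GAPDH (0.0402) passed too. With position medians removed as well, only CALM3 of these passed (0.94, adjusted p = 0.0311), and GAPDH (0.79, adjusted p = 0.0566), FAU (0.65, adjusted p = 0.0933), TNNT3 (-0.29, adjusted p = 0.350) and FTL (0.17, adjusted p = 0.543) did not. Of the 54 genes named here and in the lists below, 30 have several probes, and for 27 of them at least 1 other probe had the opposite sign. Of the 34 probes listed for MYLPF 13 had positive and 21 negative values, of the 29 for CKM 12 and 17, of the 22 for GAPDH 13 and 9, and of the 12 for TNNT3 5 and 7, and none of these passed in the main comparison. The second probe listed for IGFBP2 was at -0.09, and 3 other probes listed for COX8H ranged from -0.44 to 0.27. The unnamed probes with the largest changes were 6710 (1.10, SE 0.19) and 9211 (0.99, SE 0.18), higher, and 6811 (-1.42, SE 0.24) and 6170 (-1.34, SE 0.19), lower in destructured muscle.

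None of the 7 gene lists with at least 5 measured genes differed between the groups by camera, where the smallest adjusted p was 0.325 (0.424 with an estimated correlation). That list was the citric acid cycle and fatty acid oxidation, with a mean log2 fold change of -0.19 over 9 genes, 3 positive and 6 negative. None of its genes passed, over all probes or adjusted over the list alone; the probes listed for HADHA (-0.51), IDH3B (-0.39) and IDH2 (-0.24) had its smallest p. With position medians removed HADHA was at -0.10 (SE 0.18), IDH3B at -0.47 (SE 0.20) and IDH2 at -0.080 (SE 0.13), and without the right part of normal replicate 3 they were at -0.45 (SE 0.16), -0.13 (SE 0.13) and -0.26 (SE 0.14). Its unadjusted camera p was 0.0464. By fry, which asks whether the genes move one way on balance and does not compare them with other genes, its adjusted p was 0.0173. On the deposited scale camera called it too (adjusted p = 0.0337), where its mean was 0.00012 and the median of all probes was 0.21, so it was low only relative to the other probes. Camera did not call this list without the right part of normal replicate 3 (adjusted p = 0.304), with position medians removed (0.489) or with both (0.587). It passed in 2 of 32 alternatives. No other list passed by either test.

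Of the 13 measured glycolysis and glycogen genes 6 had positive and 7 negative values (mean -0.07, adjusted p = 0.655), and none passed. Means, signs and tests of a list rest on the brightest probe of each gene, while the members named by the rule have the smallest p over all probes of a gene, so a named probe may lie outside the list. In glycolysis the named probes listed for GAPDH (0.69), TPI1 (0.53) and PFKM (-0.31) did not enter the list, which took other probes of these genes, at 0.26, 0.21 and 0.41. The 8 fast fibre genes, 6 positive and 2 negative, had a mean of 0.14 (adjusted p = 0.595); the list's own probes for TNNI2, TNNT3 and MYLPF were at 0.10, 0.32 and 0.12, unlike the named ones above. The 7 slow fibre genes, 4 positive and 3 negative, had a mean of -0.04 with a median of 0.0056 (adjusted p = 0.655). The named probe listed for TNNT1 (-0.42) is the list's own, and those for MYH7 (0.56) and MYL2 (0.37) are not; the list held 0.033 and 0.013 for them. The 7 sarcomere genes had a mean of 0.0092 and a median of -0.04 (adjusted p = 0.831), with ANKRD1 at 0.36; the named probes listed for TPM2 (-0.30) and MYOZ1 (-0.15) did not enter the list, which held -0.042 and -0.13 for these genes. Of the 9 redox genes 5 were positive, with a mean of 0.07 (adjusted p = 0.648); TXNIP passed over all probes, TXNIP and FTL passed adjusted over the list alone, and SOD1 came next (-0.19). The 21 ribosomal genes had a mean of -0.06, with 8 positive and 13 negative (adjusted p = 0.655), and FAU alone passed adjusted over the list alone; the called probe listed for RPS3 is not the brightest of its gene and so did not enter the list, which held 0.040 for it.

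Lists with fewer measured genes were not tested. The values given for them are those of the probe with the smallest p, which need not be the brightest one of its gene. The 4 measured genes of mitochondrial respiration included NDUFA4 (0.48), COX7A1 (-0.26) and NDUFB6 (-0.13). The 4 of calpains and cathepsins included the muscle calpain CAPN3 (-0.61, SE 0.30), CTSD (0.33) and CAPNS1 (-0.21), and the 4 translation factors included TPT1 (-0.55), EEF1A1 (-0.31) and EEF1G (-0.17). The 3 chaperones were HSP90AA1, HSP70.2 (-0.37) and HSPE1 (0.33), and the 3 matrix genes FN1 (-0.34), MGP (-0.58) and MMP2 (-0.14). In the lists with 2 measured genes stood CALM3 and RYR1, the calcium release channel of muscle (0.28), then PSME3 (-0.27) and PSME1 (-0.42), BTG2 (0.16) and NFKBIA (0.06), the adipocyte markers FABP4 (0.28) and PPARG (0.06), and the immune markers CXCL12 (-0.30) and CD74 (0.02). The 1 endothelial marker was PECAM1 (-0.03). For several genes of these lists other probes had the opposite sign. Among them, the other probes ranged from -0.34 to -0.0036 for RYR1, from -0.21 to 0.30 for TPT1 and from -0.23 to -0.024 for HSPE1. The other probe stood at 0.31 for COX7A1, 0.16 for CAPN3 and 0.039 for PSME1. Only CALM3 passed adjusted over its list alone, and none passed over all probes. No gene of the blood and nerve lists was measured.

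Over all probes, pigs of different groups were farther apart than pigs of the same group. The mean distance between groups exceeded that within groups by 0.139 (exact one-sided permutation test, p = 0.00117, all splits of the 14 pigs). The difference passed in all 26 alternatives run (p from 0.000583 to 0.0256), with the highest p on the deposited scale and with median centring. The deposited scale and median centring give the same value by construction, since a constant shift of a column leaves a correlation unchanged. They are therefore not separate checks. The first principal component held 34.5% and the second 14.0% of the variance between pigs.

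The left and right parts of an array correlated across probes with a median r of 0.947 over the 14 pigs, from 0.380 in normal replicate 3 to 0.963, and the next lowest was 0.868; probes are not independent replicates. The median standard deviation between parts was 0.385 on the log2 scale, against 0.317 between the averaged pigs of a group. Without the right part of that replicate these were 0.30 and 0.265.

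**Figure D2:**
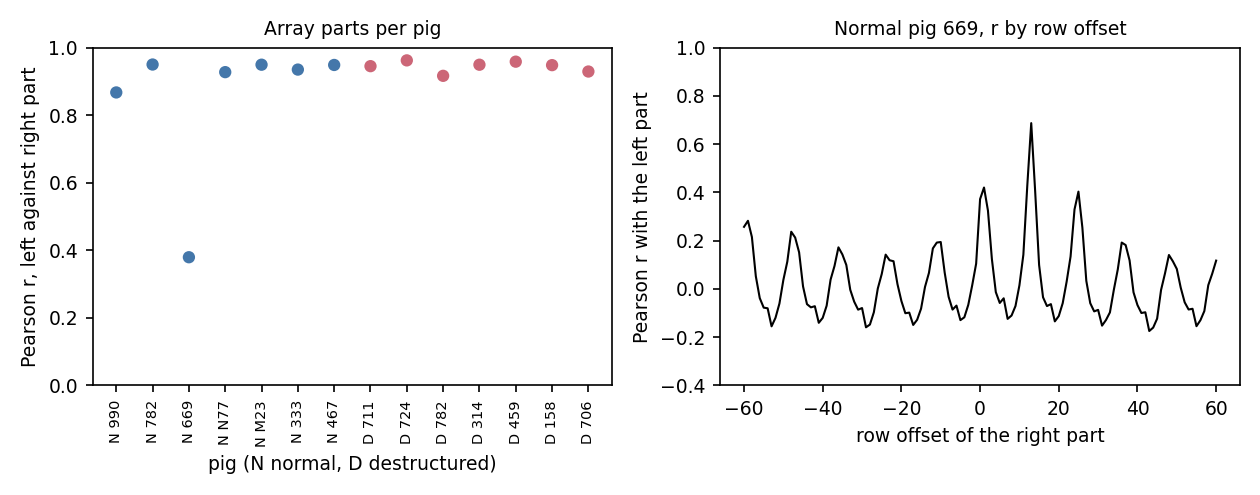
Left panel, Pearson correlation across 4608 probes (y axis) between the left and right part of each pig's array, with 7 normal pigs (N, blue) and 7 destructured pigs (D, red). Right panel, for normal replicate 3, the correlation with the left part (y axis) when the right part is displaced by a number of table rows (x axis); it was 0.373 on log2 values as deposited and reached 0.688 at an offset of 13 rows.

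The fold change followed the place of a probe in the table. Positions repeat every 72 rows, as 6 rows of 12 columns, and they held 27.3% of the variance of the fold change over probes, where shuffled probes gave at most 2.44%. Columns 2 to 7 averaged 0.11 and held 27 of the 30 called probes, and the remaining columns averaged -0.11 and held 3.

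**Figure D3:**
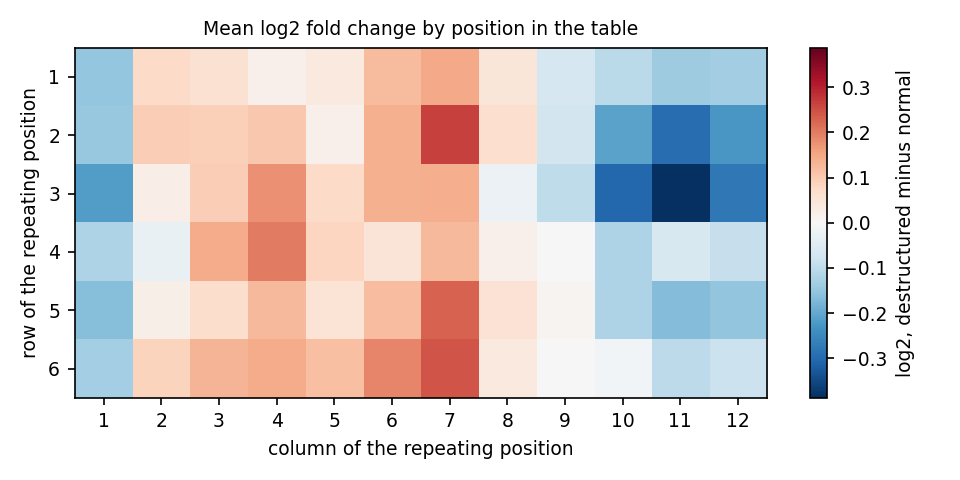
Mean log2 fold change, destructured minus normal (colour), of the 64 probes at each of the 72 repeating positions of the table, laid out as 12 columns (x axis) and 6 rows (y axis). The means ran from -0.39 to 0.26, with columns 2 to 7 mostly positive and columns 10, 11, 12 and 1 negative.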

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

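The tests on normal replicate 3 were chosen after its array was seen. In groups of 7 pigs, a pig was singled out when its gap to the nearest other pig was a large part of the group's range; this was met in 14 of 112 groups, where chance gives about 1 in 20.

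The correlation of the array parts was 0.380 in normal replicate 3, while the nearest normal pig had 0.868. The same animal stood apart from the other normal pigs in the log2 value of the probes listed for FAU (-0.58), CALM3 (2.57), TPI1 (1.92), PFKM (1.14), NDUFA4 (2.55), IDH3B (3.08), HSP70.2 (1.01) and EEF1G (2.75). The right part of its array correlated at most at 0.397 with any other column, where all other columns correlated with each other at 0.806 or more. A candidate explanation is a quantification grid displaced on the membrane. In 24 of 24 stretches of 192 rows the same offset of 13 rows gave the best match with the left part, with r from 0.536 to 0.752. This stays below the 0.868 or more of the other pigs. A fixed row offset can pair wrong spots at the edges of the repeating positions. The shortfall therefore does not tell whether a displacement alone accounts for the difference. Whether the part comes from another pig could not be told. After moving it back, its deviations from the probe means correlated at 0.038 with its own left part, rank 4 among the left parts of the 14 pigs, and at most at 0.177 with another pig, below the 0.255 that another right part reached with a pig not its own; that last bound was added after the rank was seen. Of the other 13 right parts 12 correlated highest with their own left part. With the part moved back 41 probes were called, 18 of them among the 30. The design gives no biological explanation for a difference between parts of 1 array, and none was tested.

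The other pigs that stood apart were destructured replicate 7 for the probes listed for IGFBP2 (4.53, the nearest pig at 2.79) and BTG2 (2.05), normal replicate 4 for BTG2 (1.596), and normal replicate 6 for HADHA (2.89, the nearest pig at 3.78) and PECAM1 (-0.53).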

How the results depend on the processing

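The settings on the right part of normal replicate 3, positions and array brightness were chosen after seeing the data. Against 30 calls, the count was 2 on the deposited scale (median of all probes 0.21), 6 with median centring, 49 and 56 without the dimmest 25% and 50% of probes, 13 and 1 from the left and right part alone, 3 without the 2 samples that share a pig number, 53 with the offset, 6 with trend and robust variances, 129 with array weights and 111 at a threshold of 0.10. It was 135 without the right part of normal replicate 3, 5 with position medians removed, 17 with both and 1 with brightness in the fit. With the array part as a replicate block and the pig as a random block it was 107, with no list called; the part number marks sides of 1 array and pairs no pigs across groups. An ordinary equal-variance test gave 29 and the moved-back part 41. Fewer probes tested and a looser threshold act by construction, and fewer pigs lower the power, which does not account for the higher counts without normal replicates 1, 3 and 7; otherwise the cause was not tested. Without single pigs it ran from 2 to 84: normal replicates 1, 2, 3, 4, 5 and 7 gave 56, 3, 84, 4, 5 and 80, and destructured replicates 1, 2, 3, 4, 5 and 7 gave 14, 4, 2, 9, 3 and 4, in that order. 1 list was called on the deposited scale and 1 with fry, against 0. The median correlation of parts moved by less than its spread between pigs in all 3 alternatives, and the separation passed in all 26.

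Log2 fold changes and list means that turned, the cause not tested unless given, were these. None was past the threshold on either side, except the citric acid cycle list, which camera called on the deposited scale (adjusted p = 0.0337). On that scale the median of all probes moved from -0.021 to 0.21, and such a shift turns values near 0, so these turns are not specific to a gene or list: the citric mean 0.00012, the glycolysis mean 0.14, the slow fibre mean 0.18, the ribosome mean 0.16, NDUFB6 0.025, IDH2 0.047, MYOZ1 0.078, SOD1 0.096, EEF1G 0.026, MMP2 0.052 and PECAM1 0.26. With median centring, CD74 -0.0083, PECAM1 0.043 and the sarcomere mean -0.0039. Without the dimmest 50% of probes, the glycolysis mean 0.050. With the offset, the sarcomere mean -0.0084. From the left part, HSP90AA1 0.041, CAPNS1 0.019, NFKBIA -0.0059, CD74 -0.19, PECAM1 0.012, the slow fibre mean 0.031 and the sarcomere mean -0.025. From the right part, TPM2 0.011 and MMP2 0.047. Without the samples that share a pig number, CD74 -0.046 and the sarcomere mean -0.0043. With array weights, EEF1G 0.067, CD74 -0.15 and PECAM1 0.0053. Without the right part of normal replicate 3, EEF1G 0.056, MMP2 0.033, CD74 -0.032 and the redox mean -0.0015; with it moved back, NDUFB6 0.079, HSPE1 -0.039 and EEF1G 0.020. With position medians removed, EEF1G 0.036, MMP2 0.15, PPARG -0.072 and the sarcomere mean -0.014; with both changes, HSPE1 -0.099, PSME1 0.11, EEF1G 0.15, MMP2 0.19, PPARG -0.13, PECAM1 0.015 and the redox mean -0.0055. With brightness, EEF1G 0.052, PPARG -0.13 and PECAM1 0.0013. With the mean of all probes of a gene, the fast fibre mean was -0.0079 and the sarcomere mean -0.059. Without single pigs, the sarcomere mean ran from -0.018 to 0.048, CD74 from -0.071 to 0.13, EEF1G from -0.25 to 0.060, NFKBIA from -0.012 to 0.15, PECAM1 from -0.11 to 0.0027 and PPARG from -0.028 to 0.22. Signal over background is not given in the files, so what it limits could not be computed.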

Other observations

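The splits of the pigs and the share held by positions were tested as set out before their results were seen; the tests of brightness, of gene names and of the pig number found in both groups were chosen after related values had been seen.

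Of 100 splits of the 14 pigs into 7 and 7, only 1, the real one, called as many as 30 probes, and the highest of the others called 1. This argues against a chance split of the pigs as the source of the count, to no finer than 1 in 100. It does not address a membrane or hybridisation difference that follows the groups. Without the right part of normal replicate 3 the real split called 135 and the highest other 2. For the gene lists, 100 of 100 splits gave as many called lists as the real one, which gave 0, and the highest other gave 0. With 0 lists called in the real split this outcome was fixed by construction and tells nothing about chance.

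The dependence of the fold change on table position was set against other splits. Positions held 27.3% of its variance, and 3 of 100 splits, the real one included, held as much (highest other 29.9%, median 16.3%), which argues against a pattern that varies between arrays whatever the group as the whole cause. A scale difference that depends on brightness stays open with all columns, since fold change and mean level correlated at 0.266 across probes, between the bounds set for it. Without the right part of normal replicate 3 that correlation was 0.0513 while positions still held 26.6%. This argues only against a linear dependence on brightness in the quantile-normalized values without that part. Quantile normalization already evens out scale differences between columns, so the correlation does not speak for the deposited scale. A membrane or hybridisation difference that happened to follow the groups, and a biological difference carried by probes that sit unevenly over the positions, were not tested and both stay open. The probe listed for TMBIM6 had a log2 fold change of -1.44 with position medians removed (adjusted p = 0.00105), and those listed for TXNIP, RPS3 and VDAC1 no longer passed. The log2 fold change went from 0.79 (SE 0.15) to 0.63 (SE 0.14) for TXNIP (adjusted p = 0.0780), from 0.69 (SE 0.14) to 0.60 (SE 0.13) for RPS3 (adjusted p = 0.0780) and from 0.78 (SE 0.17) to 0.48 (SE 0.13) for VDAC1 (adjusted p = 0.141). The folds became smaller while the SE did not grow. Both values of a probe come from the same pigs, so the SE does not measure the move between them. How far position contributed to these folds could not be told. Without the right part of normal replicate 3 as well, RPS3 passed again (0.62, adjusted p = 0.0334). TXNIP (0.46, adjusted p = 0.0933) and VDAC1 (0.43, adjusted p = 0.0930) did not.

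Probes listed for the same gene were not shown to share a level over the whole table (permutation p = 0.206). Positions held 34.2% of the variance of the level over probes. In columns 11 and 12 the levels of the 64 probes at a position had an SD from 0.14 to 0.63, against 1.14 to 1.99 in columns 2 to 7. Probes listed for HADHA, COX8H, PPP1R12A, FCN1, IDH2, PSME1 and MMP2 named above lie in column 11. Those listed for TNNT1, TPM2, PSME3 and CD74 lie in column 12. Column 1, with an SD from 0.33 to 0.67, holds those listed for HSP90AA1, COX7A1, TPT1 and EEF1G. Why levels vary so little in these columns was not tested. Whether row names are aligned with the values could not be told: differences in spot signal between clones would give a low F ratio of levels with correct names too, and across pigs, where that signal cancels, the mean correlation of probes listed for 1 gene was 0.010, between the median of shuffles, 0.0052, and the 0.055 that 5% of them exceed. Without the right part of normal replicate 3 and with position medians removed it was 0.015 (median of shuffles 0.0011, 5% exceeding 0.044). Noise of single spots as the cause of different levels was argued against by the median correlation of 0.947 between array parts over probes. Across pigs it stays open, since the deviations of the array parts correlated at only 0.140 (consensus over probes), so noise could by itself keep the mean correlation of 0.010 low. Displacing the names by each of 4607 offsets gave an F of at most 2.03, with 1201 offsets at or above the deposited order, and 4608 reversed orders gave at most 1.87; none was taken as a better order. Differences in DNA amount or length between clones of 1 gene were not tested and stay open.

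The arrays of normal replicate 2 and destructured replicate 3, which carry the same pig number, were compared after removing each group's mean. Their deviations correlated across probes at -0.11, rank 39 of the 49 between-group pairs (median 0.02, highest 0.26), which gave no sign of 1 animal under both labels. The left and right parts of 1 array correlated in their deviations from the probe means at only 0.37 in normal replicate 2 and 0.10 in destructured replicate 3. Arrays of 1 animal could therefore correlate little too, and the rank does not decide the question.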
